A study of Homo sapiens with 8 samples.

How the data were processed

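The series holds 8 samples of SCC9 cells, all from ChIP-seq with single 50 bp reads: 3 CHD4 libraries and 1 IgG library without DOC1, and the same with DOC1. The 6 CHD4 libraries each came with 1 peak list, and the 2 IgG libraries were not analysed here as samples of their own. Groups and replicate numbers were taken from the sample titles.

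Per the submitters' processing notes, reads were handled with Trimmomatic 0.33, BWA 0.7.12-r1039 and SAMtools 1.2, and peaks were called with MACS2 2.1.1.20160309 on hg19 (GRCh37). The command lines, read filters and the control given to the peak caller are not given in the sources used here. The deposited lists are in narrowPeak layout, 1 per library and not pooled. For each peak they hold the start, the end, the position of the summit and 4 statistics. The deposited fold enrichment is a ratio of the reads at the summit to the local background. The deposited significance is given as the −log10 of the p-value and of the q-value, and the largest q-value listed was between 0.00890 and 0.00972 in the 6 lists. The deposited score equalled the whole part of 10 times the −log10 q-value for 100% of the peaks of each list. These statistics belong to each peak in its own list, so they were used to describe, rank or filter peaks within a list. No read counts per region were used, so single regions were compared between libraries only by presence or absence of a peak, and whole lists by their number of peaks, covered length, median width and share of regions in 1 library alone. Median fold describes each list, and its test was run only as 1 of the 5 measures adjusted for.

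Depth, here the number of reads that the peak caller used, was reconstructed from the peak statistics. The fold was taken to be the pileup plus 1 over the local background plus 1, and the p-value a Poisson tail of the same pileup and background, as MACS2 is known to compute them, so that both could be solved together. A whole number of reads at the summit, times 1 factor per library, matched the background implied by the fold and the p-value within 0.002 reads for 99.96% of the peaks in lacZ 1 and DOC1 3, 99.97% in DOC1 1 and 100% in the other 3 lists. In simulated libraries drawn with 4000 peaks each, at least 99.8% of summit read numbers were recovered. All simulated summits held more reads than the median summit of DOC1 1 and DOC1 2 (15 reads). The simulated factors lay above those of lacZ 1 and DOC1 3. Recovery was therefore not tested for the weaker peaks or for these 2 factors. The factor was 0.476, 0.671 and 0.809 in lacZ 1, lacZ 2 and lacZ 3 and 0.562 in DOC1 3, read here as these libraries being scaled down to their control, and 1 in DOC1 1 and DOC1 2. The lowest background that recurred, divided by the shortest peak length, was 4.41 reads per kb in each of the 3 lacZ lists, which gives them controls of equal size. With the scaling of 0.704 and 0.946 read from the steps of the background in DOC1 1 and DOC1 2, the 3 DOC1 lists also gave equal control sizes. Taking MACS2's usual human genome size of 2.7e9 bp, which the sources used here do not state, the controls held 11.9 M reads for lacZ and 15.6 M for DOC1, and the ChIP libraries between 10.99 and 27.8 M. The median number of reads at a summit ranged from 15 in DOC1 1 and DOC1 2 to 38 in lacZ 1. At such numbers, a site with moderate enrichment can pass the threshold in 1 library and miss it in the next. Per the labels' protocols libraries were amplified for 18 PCR cycles, and no molecular identifiers are named there, so reads are not independent molecules.

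Peaks of the 6 lists that overlapped by at least 1 bp were merged into regions, and a library was counted as present in a region if it had a peak there. Group-specific regions are those in 3 of 3 libraries of one group and 0 of 3 of the other. Simulated lists with 200 planted regions of each kind returned 198 for DOC1, 199 for lacZ and 200 for all 6 libraries. Random placement kept each peak's length and chromosome and was repeated 100 times, with the end of the last peak on a chromosome taken as its length. Values per library were compared with two-sided exact permutation tests of the difference of means over all 20 assignments. Numbers of group-specific regions and the Jaccard index were compared over the 10 splits of the libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used, and matplotlib 3.10.9 for figures. No 2 lists held identical peaks: the highest Jaccard index of any pair was 32.3%.

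The regions named in the text follow a rule set before the data were examined, as were the tests and most alternatives. For each direction of the group-specific regions, these are the 12 whose worst rank by fold within the 3 lists is best, and for the regions in all 6 libraries the 6 with the best worst rank. The rule also asked for gene names. The only gene table at hand is of another genome build (GRCh38), so regions are named by hg19 position, and gene or promoter assignments and motifs were not analysed here. For the same reason 6 planned results were not run: the promoter share of peaks, promoters with a peak, members of gene lists with a peak, gene lists among genes with a group-specific region, and the promoter share and the motif share of group-specific regions. The alternatives tried were a stricter threshold (−log10 q-value of at least 4), lists of equal length (the top 2812 peaks by p-value), overlap of summits widened by 100 bp to either side, merging within 500 bp, reciprocal overlap of 50%, a difference of at least 2 libraries, leaving out each library in turn, and pairing libraries by number. Reciprocal overlap counted single peaks in place of merged regions, of DOC1 1 for the regions specific to DOC1 and of lacZ 1 otherwise. A peak of the other group with a smaller overlap then counted as absent. The test of median width, median fold, the share of regions in 1 library alone, the shares per chromosome, and the regions of DOC1 1 and DOC1 3 alone were examined only after the data were seen.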

Results

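CHD4 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in SCC9, an established line of squamous carcinoma cells of the tongue. CHD4 is the ATP-dependent remodelling subunit of the nucleosome remodelling and deacetylase complex (NuRD). DOC1, also known as CDK2AP1, is a small subunit of the same complex. The design asked how binding of NuRD to the genome differs between cells without DOC1 (labelled lacZ) and cells with DOC1 (labelled DOC1). Each group had 3 CHD4 libraries, numbered 1 to 3, and 1 library with control IgG. The 6 CHD4 libraries are analysed here through the authors' peak lists, 1 per library, in hg19 coordinates. The lists held between 2812 and 11032 peaks. The number of reads that the peak caller used was reconstructed from the peak statistics, under an assumed genome size. It came to about 25.03, 17.7 and 14.7 M reads for lacZ 1, lacZ 2 and lacZ 3. For DOC1 1, DOC1 2 and DOC1 3 it came to 10.99, 14.8 and 27.8 M reads. Read filters are not known, so more reads may have been sequenced. Nothing in the labels says that the numbered libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. With 3 libraries against 3, no two-sided exact permutation test can give a p below 0.1.

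The first question was whether CHD4 occupied more sites in cells with DOC1. The DOC1 lists held 7438 ± 3807 peaks (SD, n = 3) and the lacZ lists 4854 ± 2111 peaks (SD, n = 3), a ratio of 1.53. The difference of 2584 peaks was smaller than the SD of the DOC1 lists (two-sided exact permutation p = 0.4). It was 787 peaks without DOC1 3, 1563 without lacZ 2 and 4579 without DOC1 2. Lists of both groups overlapped in length, with 7834, 3448 and 11032 peaks in DOC1 1, DOC1 2 and DOC1 3 and with 7027, 2812 and 4723 peaks in lacZ 1, lacZ 2 and lacZ 3. The peaks covered 2.94 ± 2.03 Mb of the genome with DOC1 and 1.97 ± 1.14 Mb without it (SD, n = 3, exact permutation p = 0.6). Without DOC1 3 the order of the covered length turned, to a difference (DOC1 minus lacZ) of -0.12 Mb. Peaks were about equally wide, with a mean of the library medians of 323 ± 63.3 bp with DOC1 and 341 ± 49.7 bp without (SD, n = 3, exact permutation p = 0.5), and the order turned in lists of equal length, without lacZ 1 and without DOC1 2. Median fold enrichment, as the authors' peak caller scored each peak within its own list, was 5.82, 5.21 and 5.12 in DOC1 1, DOC1 2 and DOC1 3 and 5.67, 6.15 and 6.26 in lacZ 1, lacZ 2 and lacZ 3, given here only to describe each list.

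Sites that no other library shared made up a larger part of each DOC1 list than of any lacZ list. Overlapping peaks of the 6 lists were merged into 18808 regions, of which 10575 (56.2%) were found in 1 library alone. Such regions made up 42.2 ± 16.9% of a DOC1 library's regions and 13.96 ± 7.89% of a lacZ library's (SD, n = 3). Each DOC1 library lay above each lacZ library, with 28.6%, 61.2% and 36.9% for DOC1 1, DOC1 2 and DOC1 3 against 21.4%, 5.71% and 14.7% for lacZ 1, lacZ 2 and lacZ 3. The exact permutation p was 0.1, the smallest this design allows. Adjusted over the 5 measures compared per library (Benjamini-Hochberg), it was 0.5, and those of the other 4 were 0.5 for median fold and 0.6 for the rest. The difference of 28.3 percentage points was 19.5 without DOC1 2 and 42.8 without DOC1 1. Within the lacZ lists this share rose with the number of peaks, and DOC1 1 and DOC1 3 had the longest lists. List length can thus add to the difference in lists as deposited. In lists of equal length the difference was 22.4 points.

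**Figure D1:**
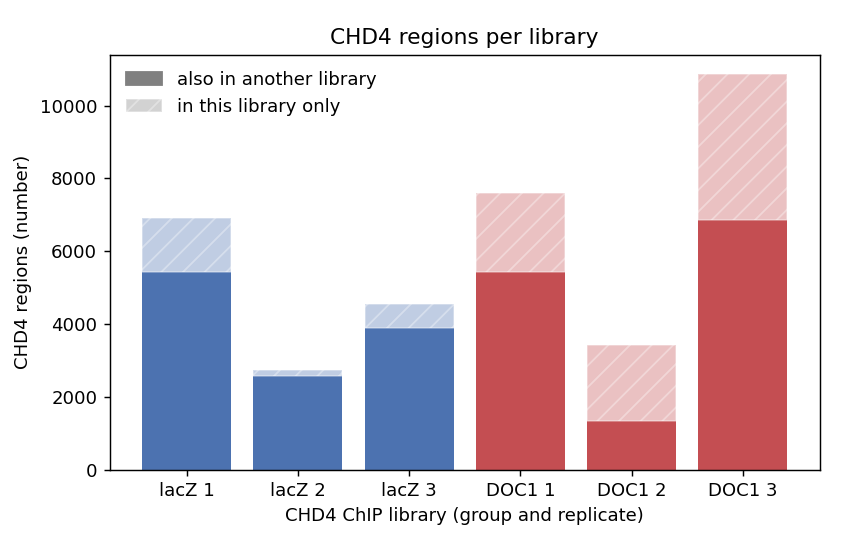
Number of merged CHD4 regions in each of the 6 CHD4 ChIP libraries (y axis), with lacZ libraries in blue and DOC1 libraries in red. The solid part of each bar counts regions also found in another library and the hatched part regions found in that library alone, which are 61.2% of the regions of DOC1 2 and 5.71% of those of lacZ 2.

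A core of CHD4 sites was occupied with and without DOC1. Peaks of all 6 libraries met in 518 regions, while random placement of the peaks on their chromosomes gave none in 100 repeats. Their median merged length was 826.5 bp, a length that grows with the number of lists merged. Their strongest peaks had a median width of 342 bp in DOC1 2 and 678 bp in DOC1 3. All peaks of these lists had medians of 284 and 396 bp. The regions ranked in the upper part of every list except that of DOC1 2. Their median fold enrichment stood at the 88.3rd percentile of the lacZ 1 list, the 72.2nd of lacZ 2, the 83.1st of lacZ 3, the 83.1st of DOC1 1 and the 93.0th of DOC1 3, but only at the 55.8th of DOC1 2. The 6 regions that ranked best in all lists lay on chromosome 20 (44599751 to 44601851), chromosome 8 (134194369 to 134195141), chromosome 4 (100481954 to 100482619), chromosome 16 (47071860 to 47072595), chromosome 19 (50178756 to 50180094) and chromosome 17 (59378390 to 59379246). The region on chromosome 20 was 2101 bp long and its fold enrichment ranged from 11.3 to 19.4 over the 6 lists. The region on chromosome 4 reached 28.5, 32.3 and 29.7 in lacZ 1, lacZ 2 and lacZ 3. In DOC1 1, DOC1 2 and DOC1 3 it reached 15.5, 9.41 and 11.7, though folds belong to their own lists. A further 678 regions were found in every library except DOC1 2, and without that library the core grew from 518 to 1196 regions. The core fell to 335 regions in lists of equal length. Reciprocal overlap, which counts peaks of lacZ 1 in place of merged regions, gave 226.

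Most sites that recurred without DOC1 were also seen with it. Of the 1874 regions found in all 3 lacZ libraries, 1653 (88.2%) held a peak of at least 1 DOC1 library. By library, DOC1 3 held 84.2% of them, DOC1 1 held 67.7% and DOC1 2 held 30.0%. Of the 1005 regions found in all 3 DOC1 libraries, 821 (81.7%) held a peak of at least 1 lacZ library. With recurrence set at 2 or more libraries of a group, 5199 regions recurred with DOC1 and 3932 without it, and 2064 recurred in both groups. At this setting 58.5% of the regions that recurred with DOC1 held a lacZ peak, below the 81.7% for all 3 DOC1 libraries, and 78.5% of those that recurred without it held a DOC1 peak. Of the regions that DOC1 1 and DOC1 3 shared, with or without DOC1 2, 2900 held a lacZ peak and 2000 did not.

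CHD4 sites found in every DOC1 library and no lacZ library numbered 184. Their median length was 562 bp, and their median fold enrichment stood at the 64.2nd percentile of the DOC1 1 list, the 47.7th of DOC1 2 and the 77.7th of DOC1 3. The site with the best rank lay on chromosome 20 (31989052 to 31989573), with folds of 13.8, 10.0 and 11.8 in DOC1 1, DOC1 2 and DOC1 3. It was followed by a site on chromosome 19 (54618554 to 54619305), with folds of 11.9, 10.1 and 16.3. Next came sites on chromosome 17 (43212647 to 43213154), chromosome 4 (77997095 to 77997550), chromosome 11 (8008430 to 8008908), chromosome 11 (518422 to 519180), chromosome 10 (114206644 to 114206986), chromosome 8 (144629232 to 144629942), chromosome 2 (191184406 to 191184889), chromosome 6 (28192835 to 28193338), chromosome 20 (23128481 to 23129164) and chromosome 1 (154580701 to 154581200). All 12 kept this pattern with summits in place of whole peaks and after merging within 500 bp. Leaving out a library loosens the rule, since fewer libraries are asked for, and can by itself raise the count. The rise was largest without DOC1 2, where 2001 regions were found in both other DOC1 libraries and no lacZ library. Without lacZ 1 the count was 309, and without DOC1 1 it was 288.

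CHD4 sites found in every lacZ library and no DOC1 library numbered 221. They had a median length of 494 bp and stood at the 73.0th, 53.4th and 63.3rd percentiles of fold enrichment in lacZ 1, lacZ 2 and lacZ 3. The site with the best rank lay on chromosome 1 (232980342 to 232980934), with folds of 17.0, 13.5 and 14.1 in lacZ 1, lacZ 2 and lacZ 3. A site on chromosome 2 (27357509 to 27358180) followed, with folds of 10.5, 11.3 and 11.8. The others were on chromosome 17 (13251225 to 13251892), chromosome 2 (8738470 to 8738944), chromosome 3 (58257722 to 58258171), chromosome 1 (16111706 to 16112146), chromosome 7 (157101535 to 157102173), chromosome 7 (130523415 to 130523927), chromosome 4 (40701574 to 40702052), chromosome 7 (1396577 to 1397462), chromosome 12 (132316062 to 132316415) and chromosome 19 (45829642 to 45830077). All 12 kept the pattern with summits, and 11 of them after merging within 500 bp. With the rule loosened in the same way, the count was 672 without lacZ 2, 353 without lacZ 3 and 570 without DOC1 3. No single region can pass a test here, since presence in 3 of 3 libraries against 0 of 3 gives a Fisher's exact p of 0.1. Absence from a list means only that no peak passed the peak caller's threshold there.

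The number of such sites was then compared with that from other ways of dividing the 6 libraries. Lists as deposited gave 405 sites specific to lacZ or DOC1, and 1 other split gave more. This split set lacZ 1, DOC1 1 and DOC1 3, which have the longest lists, against the other 3 libraries and gave 591 sites. When each list was reduced to its top 2812 peaks by p-value, the lacZ and DOC1 split gave 444 sites and the highest of the 9 other splits gave 61. The lacZ and DOC1 split was also the only one that parted the libraries by the size of their control, 11.9 M reads for lacZ and 15.6 M for DOC1. In these lists of equal length, 337 sites were found in every lacZ list and no DOC1 list, and 107 the other way. Lists as deposited gave 221 and 184. Cutting the longer lists itself makes absences, so some of these sites may hold a peak of the other group in lists as deposited. With DOC1 2 left out of the lists of equal length, 354 sites were found in all lacZ libraries and no DOC1 library, and 398 in both DOC1 libraries and no lacZ library.

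**Figure D2:**
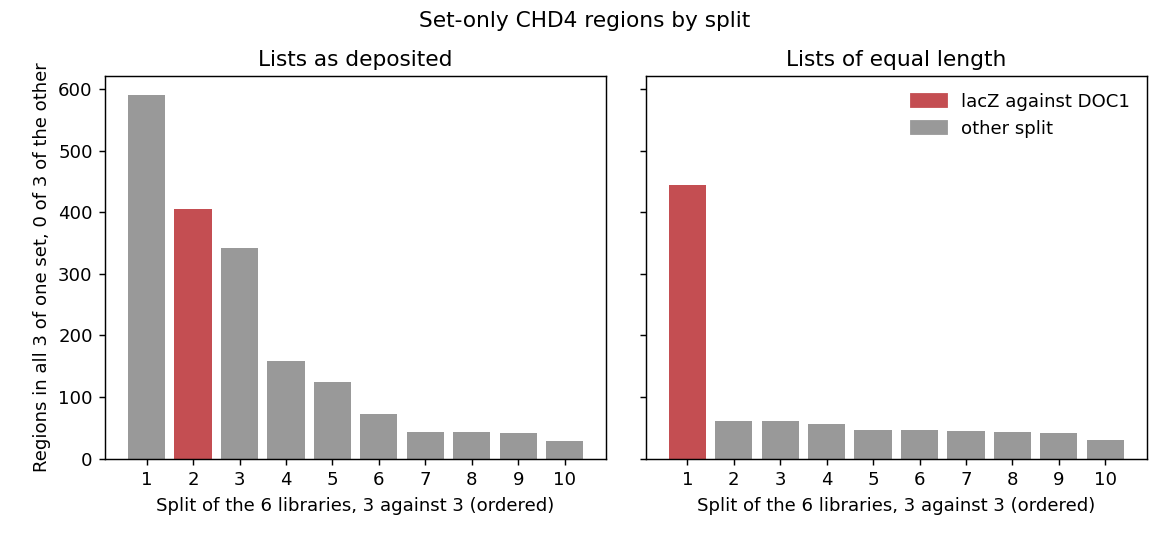
Number of regions found in all 3 libraries of one set and none of the other (y axis, both directions summed) for each of the 10 splits of the 6 libraries into 3 and 3 (x axis, ordered by that number), for lists as deposited (left) and lists of 2812 peaks each (right). The lacZ against DOC1 split (red) gave 405 regions on the left, below 591 for another split, and 444 on the right, where the other splits gave at most 61.

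On average the lacZ lists overlapped each other more than they overlapped the DOC1 lists. The DOC1 lists did not on average, and the low values among them were those of the pairs with DOC1 2. The Jaccard index, the share of the base pairs covered by either list that both lists cover, averaged 22.1% over the 6 pairs within a group and 15.0% over the 9 pairs between groups. The difference of 7.04 percentage points was the largest of the 10 splits (exact one-sided p = 0.1, the smallest possible), the highest other split giving 4.59. The 3 lacZ pairs averaged 29.9%, between 25.3% and 32.3%, and the 3 DOC1 pairs averaged 14.2%, below the pairs between groups. DOC1 1 and DOC1 3 shared 26.5%, as much as lacZ 1 shared with DOC1 3 (26.5%), and lacZ 1 shared 25.3% with lacZ 2. DOC1 2 shared 9.25% with DOC1 1 and 7.03% with DOC1 3, and between 7.65% and 9.62% with the lacZ libraries. The difference was 1.74 points without lacZ 3, 2.46 without lacZ 2 and 5.19 without lacZ 1, where other splits gave as much (exact one-sided p = 0.4, 0.5 and 0.2), and 10.9 without DOC1 2 and 11.6 without DOC1 3. It was 4.63 points where summits replaced whole peaks and 9.11 points in lists of equal length. Lists that cover unequal lengths cannot reach a high index, however alike they are. The covered length was 3.23 Mb in lacZ 1, 1.01 Mb in lacZ 2, 1.09 Mb in DOC1 2 and 5.12 Mb in DOC1 3. The values of single pairs therefore do not rank their likeness.

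The share of CHD4 peaks on single chromosomes differed between the groups by a few percentage points at most. Chromosome 19, which is dense in genes, held 6.53 ± 0.40% of the peaks without DOC1 and 4.37 ± 1.35% with it (SD, n = 3). Chromosome 6 held 7.00 ± 0.24% without DOC1 and 8.85 ± 0.99% with it, and chromosome 2 held 7.68 ± 0.37% and 8.76 ± 0.22% in the same order (SD, n = 3). In all, the 3 DOC1 libraries lay above the 3 lacZ libraries on 3 of 23 chromosomes (2, 5 and 6) and below them on 5 (12, 16, 19, 20 and 22), where chance gives 10% of chromosomes in either direction together. The exact permutation p of each was 0.1, and 0.288 after Benjamini-Hochberg adjustment over the 23 chromosomes, so none passed the test. The shares within a library depend on each other, so chromosomes are not independent and their number was not tested against chance. Without DOC1 2 the counts were 6 above, with 2, 5 and 6 among them, and 6 below, with the same 5 among them, where chance gives 20% of chromosomes. Without DOC1 3, 5 lay above, and without DOC1 1, 8 lay below. Chromosome 13 held 7.42% of the peaks of DOC1 2 and between 1.32% and 1.57% of those of the other 5 libraries.

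**Figure D3:**
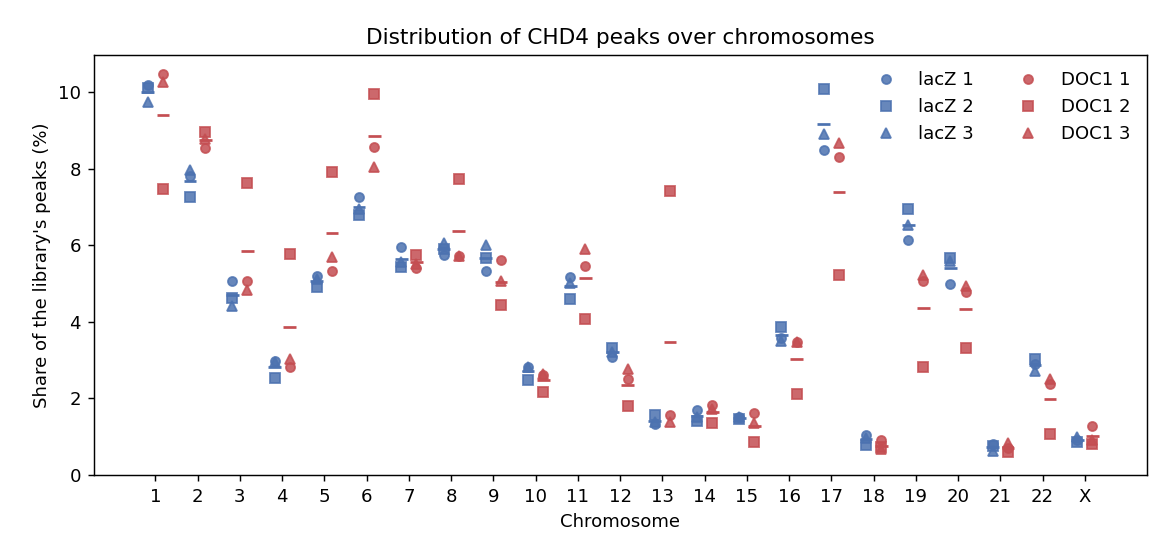
Share of each library's CHD4 peaks (y axis, percent) on chromosomes 1 to 22 and X (x axis), with lacZ libraries in blue, DOC1 libraries in red, symbols for the replicate numbers and a line at each group's mean. The DOC1 libraries lie below the lacZ libraries on chromosome 19, and DOC1 2 stands apart on chromosome 13 with 7.42%.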

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

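Settings chosen only after the data were seen are lists of equal length combined with leaving out DOC1 2, and those for chromosomes, named regions, regions in 1 library alone, peak width, fold and the regions of DOC1 1 and DOC1 3 alone. The 184 regions of every DOC1 library and no lacZ library became 107 in lists of equal length. They became 2297 with a difference of 2 or more libraries, and between 190 and 2001 when 1 library was left out. Reciprocal overlap gave 116 peaks of DOC1 1, a unit other than merged regions. The 221 regions of every lacZ library and no DOC1 library became 337 in lists of equal length, where cutting the longer lists makes absences. They became 1260 with a difference of 2 or more libraries, and between 224 and 672 when 1 library was left out. The order of both counts turned in lists of equal length without DOC1 2 (398 and 354, with DOC1 then at 2 of 2 libraries), without DOC1 2 (2001 and 224), without lacZ 1 (309 and 265) and with a difference of 2 or more libraries. Leaving out a library loosens the rule unequally for the DOC1 and lacZ counts. The orders with a library left out therefore do not compare like with like. The 518 regions of all 6 libraries became 335 in lists of equal length and 226 peaks of lacZ 1 with reciprocal overlap, settings that tighten the rule. With 1 library left out, which loosens the rule, they became between 517 and 1196. The 1196 came without DOC1 2, where the 678 regions of all libraries but DOC1 2 count as well. How far other causes add to these changes was not tested. These counts stayed within 1.5 times under the stricter threshold, with summits and with merging within 500 bp. The difference in peaks per library ranged from 787 to 4579 with 1 library left out, and that in covered length from -0.12 to 1.89 Mb, the negative value without DOC1 3 (cause not tested). The difference in the share of regions in 1 library alone was 22.4 points in lists of equal length and 19.5 to 42.8 with 1 library left out. That in median width, -18 bp, turned to 9 bp in lists of equal length and to 10.5 bp without lacZ 1 and 1.5 bp without DOC1 2, and ranged down to -54.5 bp without DOC1 3. The overlap within groups exceeded that between groups by 7.17 points under the stricter threshold, 9.11 in lists of equal length, 4.63 with summits and 7.05 with merging within 500 bp, against 7.04, and by 1.74 to 11.6 points with 1 library left out. Same-numbered libraries did not deviate together from their group means, with correlations of -0.14, -0.10 and -0.07 across regions. These deviations also carry differences in list length and depth, so this check cannot tell whether the numbers pair the libraries. With a replicate block the difference of 2584 peaks had an exact sign-flip p = 0.25 and that of 0.97 Mb p = 0.75, where 0.25 is the smallest possible. The block was not run for the overlap of libraries, since each value there belongs to a pair of libraries, and no alternative was run for the planned results that need a gene annotation or genome sequence. With 10.99 to 27.8 M reads and 15 to 38 reads at a median summit, absence of a peak is not absence of binding.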

Other observations

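The tests of explanations in this part were chosen only after the results were seen. CHD4 sites seen in 1 group lay beside sites of the other group more often than random placement gave, though most did not. Of the 184 regions of every DOC1 library and no lacZ library, 27.7% lay within 10 kb of a region with a lacZ peak, where random placement gave 6.47% on average and at most 10.9% in 100 repeats. Of the 221 regions of every lacZ library and no DOC1 library, 40.7% lay within 10 kb of a region with a DOC1 peak, against 9.93% on average and at most 14.9%. The shares were 30.0% for the regions of DOC1 1 and DOC1 3 alone and 41.4% for those of lacZ 1 and lacZ 3 alone. The lists of the other group differ in length, so these percentages are not compared with each other. Random placement drew positions along the whole chromosome. Peaks that merely favour the same parts of a chromosome would exceed it too, so the excess does not tie these sites to each other.

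CHD4 peaks also gathered in dense domains in both groups. Regions of 2 or more libraries that lay within 10 kb of each other formed 56 domains of 5 or more regions, which held 350 of 8233 such regions (4.25%). The domain with the most regions was 48.0 kb long, on chromosome 20 (49029493 to 49077525), with 12 regions and between 6 and 12 peaks per library. Another lay close to it on the same chromosome (48894984 to 48926077), with 9 regions. A domain on chromosome 17 (74494235 to 74554096) held 11 regions and between 3 and 13 peaks per library, and one on chromosome 11 (118779725 to 118809354) held 10 regions and between 1 and 11 peaks per library. Some domains, such as that on chromosome 9 (35644593 to 35676048, with 9 regions), lay in a window of raised control background. There it was at least 9.61 times that elsewhere at the peaks of each lacZ list. Whether raised background adds to the domains was not tested. All domains were picked for their number of regions after the data were seen, and random placement was not run for them.

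DOC1 2 differed from the other libraries: of its 2089 regions found in no other library, 400 (19.1%) lay in the 10 fullest windows of 5 Mb, where random placement gave at most 7.23%, which argues against placement at random alone; at 150 such regions per library the share was 24.3% in DOC1 2 and 16.1% to 17.0% in the other 5, of which all but lacZ 2 also lay above random placement of their own regions. The windows lay on chromosome 13 between 60 and 80 Mb, on chromosome 8 (75 to 80 and 110 to 115 Mb), and on chromosomes 3 (85 to 90 Mb), 5 (25 to 30 Mb), 6 (65 to 70 Mb) and 9 (35 to 40 Mb). Extra copies of these segments in the cells may contribute in the 2 windows with at least 50 lacZ peaks (105 of the 400 regions). There the control background at lacZ peaks was at least 5.51 times that elsewhere in each lacZ list. At the unshared DOC1 2 peaks it was 8.40 times (75 to 80 Mb on chromosome 13) and 11.2 times (chromosome 9). The other 8 windows held 31 lacZ peaks. That on chromosome 13 from 65 to 70 Mb, with 41 unshared DOC1 2 regions, held no lacZ peak and so has no lacZ ratio. The rest had lacZ ratios from 1 to 6.46 (3.50 to 6.46 on chromosome 13 from 70 to 75 Mb, with 12 lacZ peaks). At the unshared DOC1 2 peaks the 8 windows had ratios of 1.12 to 1.73. These 8 windows stay open as to extra copies. Such copies do not by themselves say why DOC1 2 alone has these peaks, and a difference between its cells and those of the other libraries was not tested. A lacZ library under a DOC1 label cannot be told apart either: in lists of equal length DOC1 2 shared 70 and 88 exclusive regions with the other DOC1 libraries and at most 12 with a lacZ library, which goes with its label, but the DOC1 lists also share a control size, which keeps this open.

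DOC1 1 and DOC1 3 shared 1816 regions that were in no other list, the most of the 15 pairs of libraries, followed by lacZ 1 and DOC1 3 with 663; they ranked at the 49.4th percentile of fold in DOC1 1 and the 53.5th in DOC1 3. More reads used by the peak caller in both libraries are argued against, since DOC1 1 had an estimated 10.99 M such reads and the lowest lacZ library 14.7 M. After scaling to the control the gap was small, with 10.99 M for DOC1 1 and 11.9 M for each lacZ list. DOC1 3 stood above the lacZ lists, at 15.6 M after scaling, so this speaks only to DOC1 1. Longer lists may account for the excess: in lists of equal length the pair shared 291 exclusive regions, still the most, beside 234 for lacZ 1 and lacZ 2. The control library of the DOC1 group cannot be told apart from DOC1 itself, because the control size differed between the groups and not within them; DOC1 2, with a control of the same size, held 9.20% of the 2000 regions that DOC1 1 and DOC1 3 shared and no lacZ list had, and 28.3% of the 2900 that a lacZ list also had. A difference in CHD4 binding that comes with DOC1 stays open and was not tested apart from the control.

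The rank of the lacZ and DOC1 split among the 10 splits differed between lists as deposited and lists of equal length. Its own count went from 405 to 444, where cutting the longer lists also makes absences. In lists as deposited, 2 of the 10 splits gave as many as the real 405, counting the real one, and the highest other gave 591, with the 3 longest lists on one side, which points to list length as a structure of these libraries. In lists of equal length, 1 of the 10 splits gave as many as the real 444, and the highest other gave 61. The real split is also the split by control size, so the 444 do not separate DOC1 from the control. With 10 splits a share under 0.05 cannot be reached.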
